A study of Mus musculus with 12 samples.

How the data were processed

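H3K14ac was measured by ChIP-seq in mouse neural stem and progenitor cells from the cortex and ganglionic eminences at embryonic day 14.5, either proliferating as neurospheres or plated on laminin in a medium for cortical neurons. Per the labels, the ChIP used an antibody from Abcam (ab52946), and the libraries were made with an Illumina TruSeq DNA kit and sequenced on a NextSeq. The 12 libraries were WT H3K14ac ChIP (3 per stage) and 1 library per stage each of input, IgG ChIP and H3K14ac ChIP from Hbo1 null cells. The study's description names 4 foetuses of wild type, and the input columns carry the replicate number 1 of their stage. No label says which culture or animal a replicate number stands for. The p-values thus measure only the spread between libraries, which may be technical in part. Counts of single-copy Y chromosome genes argue against 1 pool of cells per stage. Per 1e6 gene body counts they were 62.1, 15.3 and 13.9 in proliferating and 14.9, 15.6 and 275 in differentiating WT libraries.

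The authors converted the reads with bcl2fastq, and counted them with featureCounts on mm10; no version and no aligner was given in the labels used here. The deposited values are raw counts per gene in 2 tables of 27095 Entrez gene IDs by 12 libraries. One holds counts in TSS windows of 1000 bases and the other counts over gene bodies. The 24 deposited files of raw counts per sample were equal to the columns of these tables. Gene bodies include the TSS window, so the tables are not independent, and for the 3565 genes of at most 1000 bases the 2 counts were equal. Of the gene IDs 25204 were matched to a symbol and coordinates in RefSeq for GRCm38 (mm10) and 1891 were not. How reads that align to several places were treated is not stated, so values of multi-copy families were read with that limit.

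Gene body totals ran from 64071 (null, proliferating) to 17074249 (WT, differentiating), and TSS totals from 1815 to 585347. The differentiating WT libraries held more counts than the proliferating ones. A TSS window held on average 0.0933 and 0.483 expected counts at the depth of the null libraries, in which 94.8% and 75.8% of windows were at 0. Kat7 counts in the null libraries are given with 95% exact Poisson intervals, and their TSS shares with exact binomial intervals.

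Differential signal was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit and test, two-sided, prior count 0.125), with p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. Genes with a mean count of at least 10 over the libraries of the fit were tested. The stage comparison used the 6 WT libraries with TMM scaling. Each comparison with a control used the 6 WT and 2 control libraries with a stage term and gene body totals as library sizes without TMM, because a background library need not share unchanged regions with a ChIP. There the 2 control libraries, 1 per stage, stand as a group, and leaving 1 out assumes that the other varies like the WT libraries. Comparisons of the same WT libraries with 3 controls are not independent. The share of gene body counts in TSS windows was compared by exact permutation of libraries. Counts are given as CPM, scaled to 1e6 counts with the scaling of the fit, which for the controls is the gene body total.

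The 20 gene lists (neural stem and progenitor, neuronal differentiation, synapse and ion channel, oligodendrocyte lineage, astrocyte, cell cycle, housekeeping, HBO1 complexes and other histone acetyltransferases, immediate early, Hox and other lineage transcription factors, liver, striated muscle, blood cells, germline, microglia, endothelial, mesenchymal and meningeal, imprinted, chemosensory receptors, replication-dependent histones) were written before the data were examined. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, for the stage comparison and for WT against null and input, not against IgG. Adjustment was over the lists. The test was repeated with a correlation estimated per list, and that adjusted p is given wherever it ends a call. Members called among all genes and among the list alone are both given.

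The genes named were chosen by a rule fixed before the data were examined. They had an adjusted p under 0.05, a mean count of at least 30, no overlap between the groups, and a symbol that is not a predicted, clone or microRNA name. The 10 largest rises and 10 largest falls were named for the stage comparison, 5 and 5 for each control, and up to 4 members per list with the smallest adjusted p, with Kat7 throughout. Where none passed, the 5 with the smallest p are given and said not to pass. The Zfp521 and 4833417C18Rik windows, the conserved gene families and single input or IgG values were chosen after the data were seen.

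Settings were tested on simulated data at the depth of each comparison, with 200 changed genes. At folds of 1.5, 2 and 4, the stage test called 0%, 28.4% and 100% of the changed TSS windows (5 false calls) and 44.8%, 70.1% and 97.0% of gene bodies (14). Against input it called 1.49%, 14.9% and 100% of windows (3) and 47.8%, 73.1% and 97.0% of bodies (21). Against IgG it called 0%, 2.99% and 40.9% of windows (1) and 28.4%, 61.2% and 90.9% of bodies (8). Against null it called 0%, 0% and 0% of windows (0) and 1.49%, 7.46% and 31.8% of bodies (0).

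Alternatives fixed before the data were examined were RLE scaling, library totals, gene body totals, DESeq2 1.42.0, no count filter and a mean of at least 50, a replicate block, adjustment for input or null libraries, all 12 libraries in 1 fit, no stage term, leaving out each library, fry in place of camera, and a median over genes in place of the ratio of totals. Autosomes alone, thinning to a common depth (with the count filter applied anew, or with the regions of the reported test), gene bodies without the TSS window and list tests without each library were added after the data were seen. No peaks were called and no reads were aligned, since no genome or reads were at hand, and no expression data were part of the series.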

Results

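Acetylation of histone H3 at lysine 14 (H3K14ac), a histone mark made by the acetyltransferase HBO1 (gene Kat7) among other enzymes, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse neural stem and progenitor cells. The cells came from the forebrain of embryos and were grown as neurospheres, floating clusters of dividing cells. They were sampled while proliferating, or after transfer to laminin in a neuron culture medium, here called differentiating. The 12 libraries were 6 wild-type (WT) H3K14ac ChIP libraries, 3 per stage, and 6 controls: 1 input, 1 IgG ChIP and 1 H3K14ac ChIP from Hbo1 null cells at each stage. Input is chromatin sequenced without immunoprecipitation, IgG is a non-specific antibody, and the null cells were included as cells without the mark. No control had a replicate within its stage. For each of 27095 genes the reads were counted in a window of 1 kb that starts at the transcription start site (TSS window) and over the whole gene (gene body, which contains the TSS window). Gene body counts summed to 4542787, 3992697 and 7611239 in the proliferating WT libraries and to 12549913, 12782070 and 17074249 in the differentiating ones. The input libraries held 11871306 (proliferating) and 12689734 (differentiating) counts and the IgG libraries 2526252 and 2771713. The null libraries held only 64071 and 320601, so single genes could hardly be measured in them.

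Kat7, the gene deleted in the null cells (gene ID 217127, chromosome 11, 95271853 to 95310246, GRCm38), was looked at first in every library. Its gene body held 30.2, 32.8 and 26.9 CPM (counts scaled to 1e6 gene body counts) in the proliferating WT libraries and 32.2, 37.9 and 35.6 in the differentiating ones. The values were 47.2 and 44.5 in input and 47.5 and 41.1 in IgG. The null libraries held 4 counts (62.4 CPM, 95% exact Poisson interval 17.0 to 160) and 11 counts (34.3 CPM, 17.1 to 61.4). These are counts of precipitated DNA over the whole gene, so they check neither which part of the gene was deleted nor whether it was expressed. The Kat7 TSS window fell between proliferating and differentiating WT cells (log2 −1.17, SE 0.34, edgeR adjusted p = 0.0213, n = 3 each). It held few counts: 10, 10 and 23 in the proliferating and 12, 13 and 10 in the differentiating WT libraries. The window was lower in input too, at 15 counts (1.26 CPM) in proliferating and 9 (0.709 CPM) in differentiating cells. A fall already present in the input is thus not excluded.

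The share of gene body counts that lies in TSS windows shows how far a library is concentrated at the starts of genes, and it needs no scaling between libraries. It was 4.56%, 4.90% and 4.85% in the proliferating WT libraries and 3.68%, 3.24% and 3.43% in the differentiating ones. The inputs held 3.36% (proliferating) and 3.23% (differentiating), the IgG libraries 3.34% and 2.90%, and the null libraries 2.83% (95% exact binomial interval 2.71 to 2.96) and 2.93% (2.87 to 2.98). H3K14ac ChIP of WT cells was thus more concentrated at gene starts than the 6 controls, by 1.01 percentage points (4.11 ± 0.748 against 3.10 ± 0.238, SD, n = 6 each, two-sided exact permutation p = 0.00866). Against each kind of control alone, with 2 libraries, no exact permutation p passed (0.107 for null, 0.179 for IgG and 0.179 for input, where 0.0357 was the smallest possible). The proliferating libraries alone lay above the controls (exact permutation p = 0.0119, the smallest that 3 against 6 allow), and the differentiating libraries alone did not pass (difference 0.350 points, exact permutation p = 0.0595). The differentiating mean of 3.45 ± 0.220 lay 1.32 points below the proliferating mean of 4.77 ± 0.185 (SD, n = 3 each), with no overlap, at the smallest two-sided exact permutation p that 3 against 3 allow, 0.1. Divided by the input of the same stage, the share was 1.36 to 1.46 in proliferating and 1.00 to 1.14 in differentiating WT cells, and 0.843 and 0.907 in the null libraries. Without the 51 gene bodies described below that were higher in the null libraries, the null shares became 3.13% and 3.06%. As a median over genes of the log2 ratio of TSS to gene body counts, the difference between WT and controls was 0.05 (exact permutation p = 0.909). A small constant was added to each count there, and the median gene body of the null libraries held 0 and 3 counts. The constant thus set much of the null ratios, so this median cannot decide whether WT and controls differ.

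**Figure D1:**
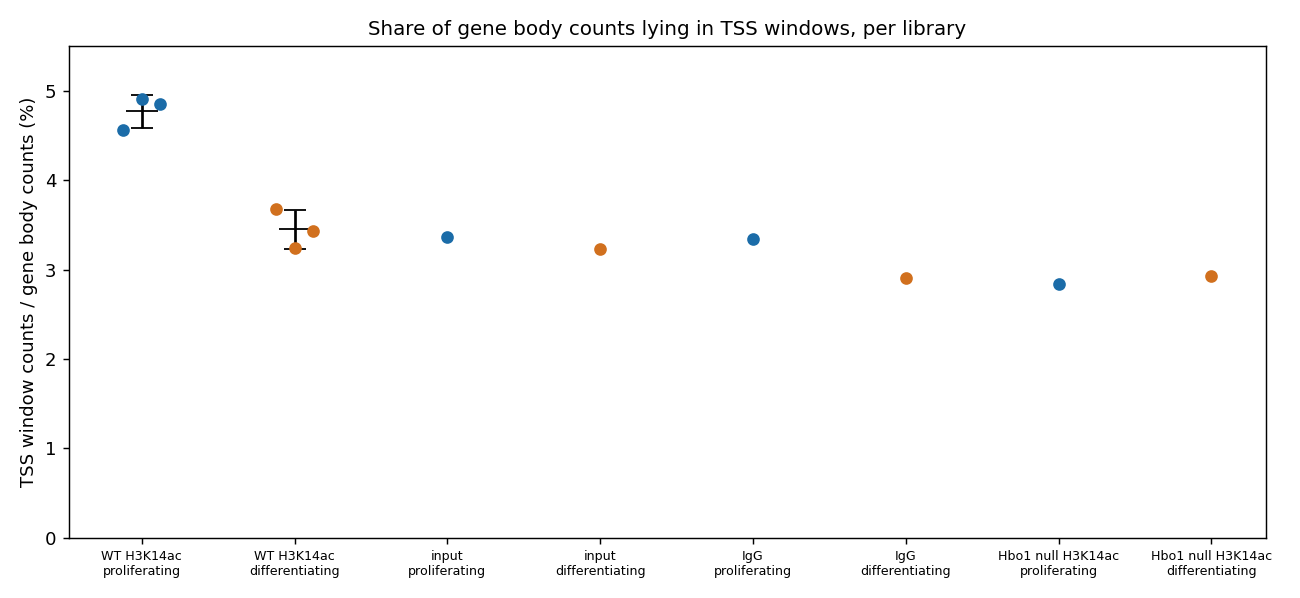
Share of gene body counts in TSS windows (percent, vertical axis) for each of the 12 libraries, by group; points are libraries, and bars are the mean and SD of the 3 WT libraries of a stage. The proliferating WT libraries sit between 4.56% and 4.90%, above every other library, and the differentiating ones between 3.24% and 3.68%.

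The comparison of WT ChIP with input asks where H3K14ac is enriched over sequenced chromatin. In proliferating cells, the gene starts of neural stem and progenitor, histone acetyltransferase, immediate early and replication-dependent histone genes stood above input in sum. As lists over both stages, these 4 lost their calls with an estimated correlation (adjusted p = 0.429, 0.541, 0.621 and 0.541 by camera). In proliferating libraries the summed TSS windows of 27 neural stem and progenitor genes held 2.83 times the input share, those of 15 immediate early genes 3.54 times (log2 1.82 ± 0.09, SD, n = 3) and those of 63 histone genes 2.78 times (1.48 ± 0.12). In differentiating libraries the same lists held 1.59 times (0.67 ± 0.20), 1.05 times (0.07 ± 0.23, within its spread of input) and 1.23 times (0.30 ± 0.25). Cell cycle genes went from 1.87 times (0.90 ± 0.09) to 0.888 times (−0.17 ± 0.07) and housekeeping genes from 2.13 (1.09 ± 0.09) to 1.14 (0.18 ± 0.16). Hox and other lineage transcription factors, which are silent in most forebrain cells, lay below input in both stages (0.585 times, −0.77 ± 0.27, and 0.797 times, −0.33 ± 0.13). The IgG libraries, set against the same inputs, stood at 0.43 and −0.23 (proliferating, differentiating) for the neural stem list and at 0.23 and −0.57 for the Hox list. Over IgG in place of input, the neural stem list held 2.11 times the IgG share in proliferating and 1.88 times in differentiating libraries. In differentiating libraries the immediate early list held 1.62 times the IgG share, histone genes 1.64, housekeeping genes 2.08 and cell cycle genes 1.14 times. Whether these lists were back at background there thus depends on the background used. The Hox list in differentiating libraries was not lower than IgG.

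**Figure D2:**
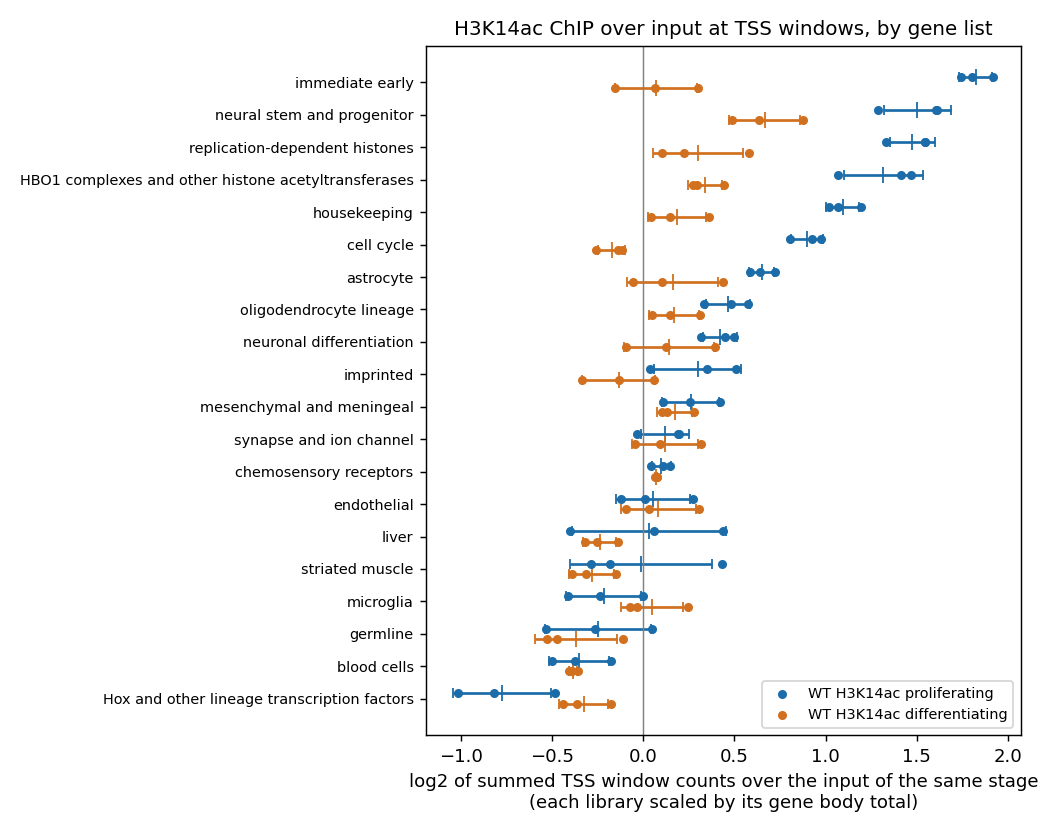
Log2 of the summed TSS window counts of each gene list over the input of the same stage, each library scaled by its gene body total (horizontal axis), for 20 gene lists (vertical axis); points are WT libraries, with the mean and SD of 3 per stage. The immediate early list goes from 1.82 ± 0.09 in proliferating to 0.07 ± 0.23 in differentiating libraries and the cell cycle list from 0.90 ± 0.09 to −0.17 ± 0.07.

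Over both stages, edgeR's quasi-likelihood test called 2507 of 21557 TSS windows higher in WT ChIP than in input and 190 lower (Benjamini-Hochberg adjusted p under 0.05, gene body totals as library sizes). The highest of the named genes were Chaserr (log2 2.57, SE 0.46, edgeR adjusted p = 3.46e-05), a long noncoding RNA gene, Dyrk1a (2.52, SE 0.46), Nfib (2.51, SE 0.46), a transcription factor of neural progenitors and glia, Abhd17b (2.50, SE 0.46) and Arid1a (2.43, SE 0.46), a subunit of a chromatin remodeler. Asmt on the X chromosome was lower (−1.22, SE 0.34). Of the 27 neural stem and progenitor windows 18 were higher and none lower (20 and 0 adjusted over the list alone), among them Vim (1.78), Msi1 (1.77), Lhx2 (1.70) and Sox1 (1.69). Among histone genes 24 of 53 were higher (37 adjusted over the list alone), with H2ac21 at 2.46 and H3c1 at 1.83. Among 16 genes of HBO1 complexes and other histone acetyltransferases 7 were higher (8 over the list alone), with Kat2b at 2.70, Brd1 at 1.78, Kat6a at 1.65 and Jade2 at 1.43. Of the 14 immediate early windows 5 were higher (9 over the list alone), with Egr1 at 1.98 and Jun at 1.72. Higher windows were found for 4 of 16 neuronal differentiation genes (Map2 1.62, Sox11 and Sox4 1.23 each, Tubb2b 1.10), 2 of 14 astrocyte genes (Fgfr3 1.79, Slc1a2 1.41), 2 of 22 synapse and ion channel genes (Homer1 and Dlg4, the latter at 1.15), 5 of 24 housekeeping genes (Actb 1.51) and 1 of 27 cell cycle genes (Ccnd1 1.56). Of 12 lineage transcription factor windows, Evx2 (−1.09) and Cdx2 (−1.03) were lower.

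Camera, which asks whether a list stands apart from all other windows, called 11 of 20 lists with a preset correlation between genes and none with an estimated one. The neural stem and progenitor (adjusted p = 2.59e-08 by camera, 0.429 as adjusted p with an estimated correlation), histone (1.44e-08, 0.541), histone acetyltransferase (0.00382, 0.541), immediate early (0.00466, 0.621) and housekeeping (0.05, 0.666) lists stood higher. The Hox and lineage factor (0.00102, 0.12), blood cell (0.00102, 0.316), germline (0.00347, 0.316), liver (0.0376, 0.588), striated muscle (0.05, 0.621) and chemosensory receptor (0.00014, 0.0587) lists stood lower than the other windows. The 1302 chemosensory windows themselves had a median log2 of 0.04 and a mean of 0.07, opposite in sign to the test, and with TMM scaling the median was −0.22, with 21 windows higher and 38 lower in place of 44 and 7. The oligodendrocyte, microglia, endothelial, mesenchymal and imprinted lists were not called and had no window past the threshold. TMM scaling moved the median of all windows from 0.25 to −0.02 and gave 1382 windows higher and 659 lower. With the proliferating input left out, so that differentiating cells alone were set against their input, 25 windows were called, all higher; with the differentiating input left out, 3899 were higher and 91 lower, and without proliferating replicate 3 or differentiating replicate 1 the totals were 1653 and 1773.

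Over gene bodies, 2094 of 24848 were higher in WT ChIP than in input and 5304 lower. Highest among the named genes were Esp36 (log2 2.34, SE 0.46), Csn1s1 (1.93, SE 0.31), Olfr77 (1.74, SE 0.35), H3f3b (1.69, SE 0.31), which encodes the histone variant H3.3, and Sox2 (1.66, SE 0.29, edgeR adjusted p = 0.0022), the neural stem cell transcription factor (chromosome 3, 34649995 to 34652461). Esp36 and Olfr77 belong to families of near-identical genes, so their counts depend on how shared reads were treated. Lowest were Polrmt (−1.28, SE 0.15), Prss53 (−1.24, SE 0.21), Hoxb9 (−1.18, SE 0.18), Wdr13 (−1.14, SE 0.27) and Smim10l2a (−1.14, SE 0.24). Neural stem and progenitor bodies were higher for 12 of 27 genes and lower for 1, with Sox1 at 1.32, Sox9 at 0.97 and Fabp7 at 0.97 (camera adjusted p = 1.12e-09, and adjusted p = 0.233 with an estimated correlation). Synapse and ion channel genes, which are long, were higher for 12 of 26 and lower for 4, with Cntnap2 at 0.51 and Scn1a at 0.42 (camera adjusted p = 0.000268, and p = 0.0665 with an estimated correlation). The summed counts of this list over input were log2 0.27 and 0.25 in WT ChIP (proliferating, differentiating) and 0.13 and 0.26 in IgG. In differentiating cells its excess was thus not particular to the H3K14ac antibody. Histone bodies were higher for 20 of 53 (camera adjusted p = 3.76e-19, and p = 0.22 with an estimated correlation).

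Of 52 Hox and lineage factor bodies 20 were lower and none higher, all 52 with a negative log2 (camera adjusted p = 3.83e-05, and p = 0.285 with an estimated correlation). Their summed counts over input were log2 −0.64 and −0.30 in WT ChIP (proliferating, differentiating) and 0.03 and −0.31 in IgG. In differentiating cells the list was thus not lower than IgG. Lower bodies also prevailed among cell cycle genes (16 of 28, with Cdc6 at −0.60; camera adjusted p = 0.00689, p = 0.0943 with an estimated correlation) and histone acetyltransferases (12 of 18, with Ing5 at −0.72; 0.00472, and p = 0.0943). Summed over input, cell cycle bodies stood at log2 −0.36 and −0.26 in WT ChIP (proliferating, differentiating) and −0.14 and −0.17 in IgG. Acetyltransferase bodies stood at −0.26 and −0.19 in WT ChIP and 0.02 and −0.15 in IgG. In differentiating cells much of both deficits was thus present in IgG too. The chemosensory list stood higher (151 of 1423 bodies higher and 10 lower, median 0.09), the one list of this comparison whose call held with an estimated correlation (camera adjusted p = 4.55e-08, then p = 0.000377). The summed counts of these bodies were as high over input in the IgG libraries (log2 0.31 and 0.43) as in WT ChIP (0.29 and 0.33), so this excess was not particular to the H3K14ac antibody. The mesenchymal list, too, was as high over input in IgG (0.16 and 0.14) as in WT ChIP (0.11 and 0.14). Camera called it (10 genes, adjusted p = 0.0497 by camera, and p = 0.22 with an estimated correlation) and the immediate early list (15 genes, 0.0446, and p = 0.714). The other lists were not: neuronal differentiation (5 higher, 2 lower of 32), oligodendrocyte (2 and 1 of 18), astrocyte (0 and 2 of 14), housekeeping (0 and 8 of 25), liver (1 and 0 of 22), striated muscle (1 and 3 of 21), blood cell (1 and 4 of 20), germline (3 and 2 of 17), microglia (0 and 1 of 10), endothelial (1 and 0 of 10) and imprinted genes (1 and 2 of 15). TMM scaling moved the median of all bodies from −0.14 to −0.03 and gave 2908 higher and 2743 lower. With the proliferating input left out no body was called (6168 at an unadjusted p under 0.05), and with the differentiating input left out 2292 were.

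The comparison with IgG asks which regions the H3K14ac antibody recovered beyond non-specific pull-down. At TSS windows, 675 of 13158 were higher in WT ChIP and 27 lower. Zfand5 had the largest rise over IgG among the named genes (log2 4.70, SE 0.88, edgeR adjusted p = 0.000162, chromosome 19, 21271786 to 21286840). It was followed by Bcl6 (3.31, SE 0.70), a transcriptional repressor, Chaserr (3.04, SE 0.65), Srf (3.00, SE 0.66), the serum response factor, and Usp7 (2.85, SE 0.69), a deubiquitinase. The listed genes above IgG included Sox3 (3.03), Egfr (2.19) and Msi1 (2.18) of the neural stem list, Ier2 (3.29), Fos (2.91) and Jun (1.87) of the immediate early list, Brd1 (2.99) and Kat6a (2.46) of the acetyltransferases, and H2ac18 (3.57) and H2bc7 (3.40) of the histones. Also above IgG were Mki67 (2.71), Sox4 (2.05), Vcp (3.99) and Hsp90ab1 (3.74). Lower than IgG were Erdr1 (−2.45, SE 0.37), Speer4cos (−1.62, SE 0.34) and Asmt (−1.20, SE 0.36), genes of multi-copy families or of the end of the X chromosome. The IgG libraries differed from most WT libraries in sex chromosome content: single-copy Y genes held 249 and 292 CPM in IgG, against 13.9 to 62.1 in 5 WT libraries and 275 in differentiating replicate 3.

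The summed counts of those 675 windows were 2.89, 3.77 and 3.29 times the input share in the proliferating WT libraries and 1.90, 1.35 and 1.54 times in the differentiating ones. They were 0.464 and 0.320 times the input share in the IgG libraries. Both the WT and the IgG libraries were used to choose the windows, which widens the gap between them. In the null libraries, which played no part in the choice, they were 0.726 times (38 counts, 95% exact Poisson interval 0.514 to 0.997) and 0.772 times (190 counts, 0.666 to 0.890). The null totals used for scaling include the 51 gene bodies described below, which held 10.6% and 4.66% of them and so lower both values. The intervals also take the input count as fixed. The upper limit of 0.997 therefore does not place the proliferating null library below input. TMM scaling, which lowered the median of all windows from 0.67 to 0.05, left 14 higher and 39 lower. Without the proliferating IgG library 5 windows were called, all lower, without the differentiating one 466 and without WT proliferating replicate 2 447.

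Over gene bodies 128 of 23685 were higher than IgG and 175 lower. The named genes that were higher were Cstdc3, which had 0 counts in both IgG libraries, Cd300ld4 (log2 5.41, SE 0.51), Trim12a (5.31, SE 0.38), Nlrp1c-ps (3.54, SE 0.17) and Skint3 (3.39, SE 0.31). Those lower were Mrgpra3 (−2.55, SE 0.14), Erdr1 (−2.33, SE 0.48), Esp34 (−1.86, SE 0.24), Vmn2r44 (−1.82, SE 0.14) and Itln1 (−1.74, SE 0.11). Most of these belong to immune, pheromone or receptor families with near-identical copies that vary in number between mouse strains. Of the neural lists Olig2 (1.27, SE 0.25, edgeR adjusted p = 0.0331) was higher, and of the other lists Btg2 (1.27) and H3c1 (2.76). The receptor genes Vmn2r49 (−1.70), Vmn2r32 (−1.33) and Vmn2r30 were lower. Leaving out 1 library gave 74 calls (without IgG proliferating), 116 (IgG differentiating), 186 (WT proliferating replicate 3), 199 (WT differentiating replicate 1) or 701 (WT differentiating replicate 3) in place of 303.

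The comparison with Hbo1 null cells asks how much of the ChIP signal needs HBO1. No TSS window or gene body was called higher in WT than in null libraries. At TSS windows edgeR called 2 of 10948 as lower in WT and none higher (92 at an unadjusted p under 0.05, and DESeq2 called 4 lower). The 92 depends on the scaling: edgeR gave 3793 such windows with TMM and 3790 with RLE, with the same 2 called. Of the tested windows 67.6% had 0 counts in both null libraries. In data simulated at this depth a 4-fold change was called in 0% of the changed windows, so a loss of H3K14ac at single genes was not detectable here. The 2 windows, Zfp521 and 4833417C18Rik, are outside the rule for named genes and are given because they are the only calls: Zfp521 held 9 and 13 counts in the null libraries (140 and 40.5 CPM) and 9 and 15 in the inputs (0.758 and 1.18 CPM). The 5 named windows with the smallest p did not pass (adjusted p = 0.453 by edgeR): Duxf3 at 2.92, and the mitochondrial genes ND3 (−1.22), ND4L (−1.17), COX1 (−1.23) and ND4 (−1.18), which turned positive with TMM scaling. The liver list (5 windows, camera adjusted p = 0.0124, and p = 0.187 with an estimated correlation; median −1.91, mean 1.34) and the endothelial list (2 windows, 0.00709, then p = 0.187) stood lower, and no other list was called. At this count level a list's fitted values depend on windows with no null counts.

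Over gene bodies 51 of 23336 were lower in WT than in null libraries and none higher (1711 at an unadjusted p under 0.05; DESeq2 called 81, all lower). Lars2, a mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366927 to 123462675), held 10473 and 5006 CPM in the null libraries, against 121 ± 4.73 (SD, n = 6) in WT ChIP, 184 and 169 in input and 180 and 151 in IgG (log2 −5.91, SE 0.15, edgeR adjusted p = 2.97e-11). Il6ra (−5.13, SE 0.21), Cndp1 (−4.51, SE 0.22), Actc1 (−4.28, SE 0.37), cardiac actin, and Itprid1 (−4.13, SE 0.23) followed. The listed genes lower in WT were Acta1 (−5.12), skeletal actin, Tubb3 (−3.49), a neuronal tubulin, and Acta2 (−2.84), smooth muscle actin. The 51 bodies took 10.6% and 4.66% of the null libraries' counts, against 0.591% to 0.642% in WT ChIP, 0.618% and 0.627% in input and 0.740% and 0.710% in IgG. Camera placed the immediate early (15 genes, adjusted p = 0.0403), chemosensory (565 genes, 0.00405) and histone lists (36 genes, 0.00127) higher in WT with none of their members called, and the adjusted p was 0.963 for each with an estimated correlation.

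Differentiating and proliferating WT cells were compared to ask how H3K14ac changes when stem cells leave proliferation. At TSS windows, signal fell at most immediate early genes, relative to the typical window, and at some histone, cell cycle, neural stem and acetyltransferase genes. As lists, the latter 4 lost their calls with an estimated correlation (adjusted p = 0.0818, 0.171, 0.251 and 0.178 by camera). Some chemosensory receptor genes and a few genes of differentiated cells rose on the same relative scale. Of 19477 windows tested, 395 rose and 890 fell (edgeR, TMM scaling, Benjamini-Hochberg adjusted p under 0.05). Per 10000 TSS counts, the 395 risen windows together held 73.2 ± 2.85 in proliferating and 191 ± 13.2 in differentiating WT libraries (SD, n = 3 each). The inputs held 143 and 167 there. These windows, chosen for their rise, thus went from below input to near it, and no gain well above background was shown. The named gene with the largest fall was Srf, the serum response factor that drives immediate early genes (gene ID 20807, chromosome 17, 46546838 to 46558267), at 63.7 ± 7.30 CPM in differentiating and 221 ± 35.9 in proliferating cells (SD, n = 3 each, log2 −1.79, SE 0.27, edgeR adjusted p = 1.08e-07). Irf2bp2 fell by 1.49 (SE 0.27), Bcl6 by 1.37 (SE 0.26), Smarca5, a chromatin remodeling ATPase, by 1.34 (SE 0.27) and Setd7, a histone methyltransferase, by 1.31 (SE 0.27) on the log2 scale. Rab6a (−1.31), Gab2 (−1.30), Purb (−1.29), Cdk17 (−1.26) and Hnrnpa2b1 (−1.26) also fell. Erdr1, at the end of the X chromosome (170010526 to 170018797), rose most among the named genes (3.81, SE 0.40, 167 ± 17.1 against 10.6 ± 9.53 CPM). Zfp981 (1.34), Zfp991 (1.01), Zfp979 (0.85) and Speer4cos (0.85) rose too. All 5 belong to multi-copy families or regions in which reads cannot be placed with certainty, and Erdr1 changed as much in input (log2 of the stage difference over input −0.07).

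The immediate early list, genes induced within minutes of a stimulus, changed most: 11 of 14 windows fell (13 adjusted over the list alone) and all 14 had a negative log2, with Fosb at −1.95 (SE 0.28), Ier2 at −1.75 (SE 0.27), Egr1 at −1.52 (SE 0.28) and Fos at −1.49 (SE 0.28). The camera adjusted p was 1.84e-12 and stayed under the threshold with an estimated correlation (adjusted p = 0.0363). Of 53 replication-dependent histone windows 15 fell and none rose (29 over the list alone), with H2ac12 at −1.66, H2bc11 at −1.61, H2ac21 at −1.56 and H3c1 at −1.37 (camera adjusted p = 1.16e-13, and p = 0.0818 with an estimated correlation). Histone genes are short and nearly identical within families. Of 25 cell cycle windows 4 fell, both over all genes and over the list alone: Mki67 (−1.42), Ccna2 (−1.33), Ccnd1 (−1.22) and Ccnb1 (−1.03); 23 of the 25 had a negative log2 (camera adjusted p = 3.46e-05, and p = 0.171 with an estimated correlation). Of 27 neural stem and progenitor windows 4 fell (6 over the list alone), Lhx2 (−1.23), Nes (−1.12), Emx2 (−0.96) and Notch1 (−0.86), with 23 negative (camera adjusted p = 0.000177, and p = 0.251 with an estimated correlation). Of 16 HBO1 complex and acetyltransferase windows 3 fell (5 over the list alone), Kat7 (−1.17), Brpf3 (−0.96) and Kat6a (−0.91), with 14 negative (camera adjusted p = 0.00506, and p = 0.178 with an estimated correlation).

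Chemosensory receptor genes, which include the olfactory and vomeronasal receptors and are silent in forebrain cells, rose relative to the typical window: 118 of 1230 rose and none fell (160 and 0 over the list alone), 1156 had a positive log2, and the median was 0.61 (camera adjusted p = 3.51e-25, and p = 0.0363 with an estimated correlation). Olfr607 (2.72), Vmn2r43 (2.14), Olfr603 (2.03) and Vmn2r76 (1.77) had the smallest p. With gene body totals as library sizes 21 rose and 7 fell, 750 were positive and the median was 0.12, and the summed share over input did not rise (1.07 times in proliferating and 1.05 times in differentiating libraries). The 5 measured Hox and lineage factor windows had a median of 0.76 and Hoxd4 rose (1.49; camera adjusted p = 0.0196, and p = 0.178 with an estimated correlation). Among 16 liver windows Cyp3a11 rose (1.41; 2 over the list alone; camera adjusted p = 0.0153, and p = 0.375 with an estimated correlation), and the list's median of 0.36 turned to −0.14 with gene body totals. Single genes of differentiated neural cells rose: Gfap, the astrocyte filament gene (1.40, SE 0.35, 61.3 ± 4.04 against 21.3 ± 7.43 CPM), Gpr17 of oligodendrocyte precursors (1.17, SE 0.34), and Syt1 (2.08, SE 0.51) and Scn2a (1.35, SE 0.44) of neurons. Homer1, also of the synapse list, fell (−1.21). With gene body totals Syt1 alone of these 4 risen genes stayed past the threshold, and Hoxd4 and Cyp3a11 did not. As lists, synapse and ion channel (2 rose and 1 fell of 18), oligodendrocyte (1 rose of 16), astrocyte (1 rose of 14), neuronal differentiation (0 of 16) and housekeeping genes (Hsp90ab1 fell, −0.98, of 25) were not called. Nor were the lists for other cell types or origins, with no window called: striated muscle (13 windows), blood cells (7), endothelial (7), germline (6), microglia (6), mesenchymal (6) and imprinted genes (9).

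**Figure D3:**
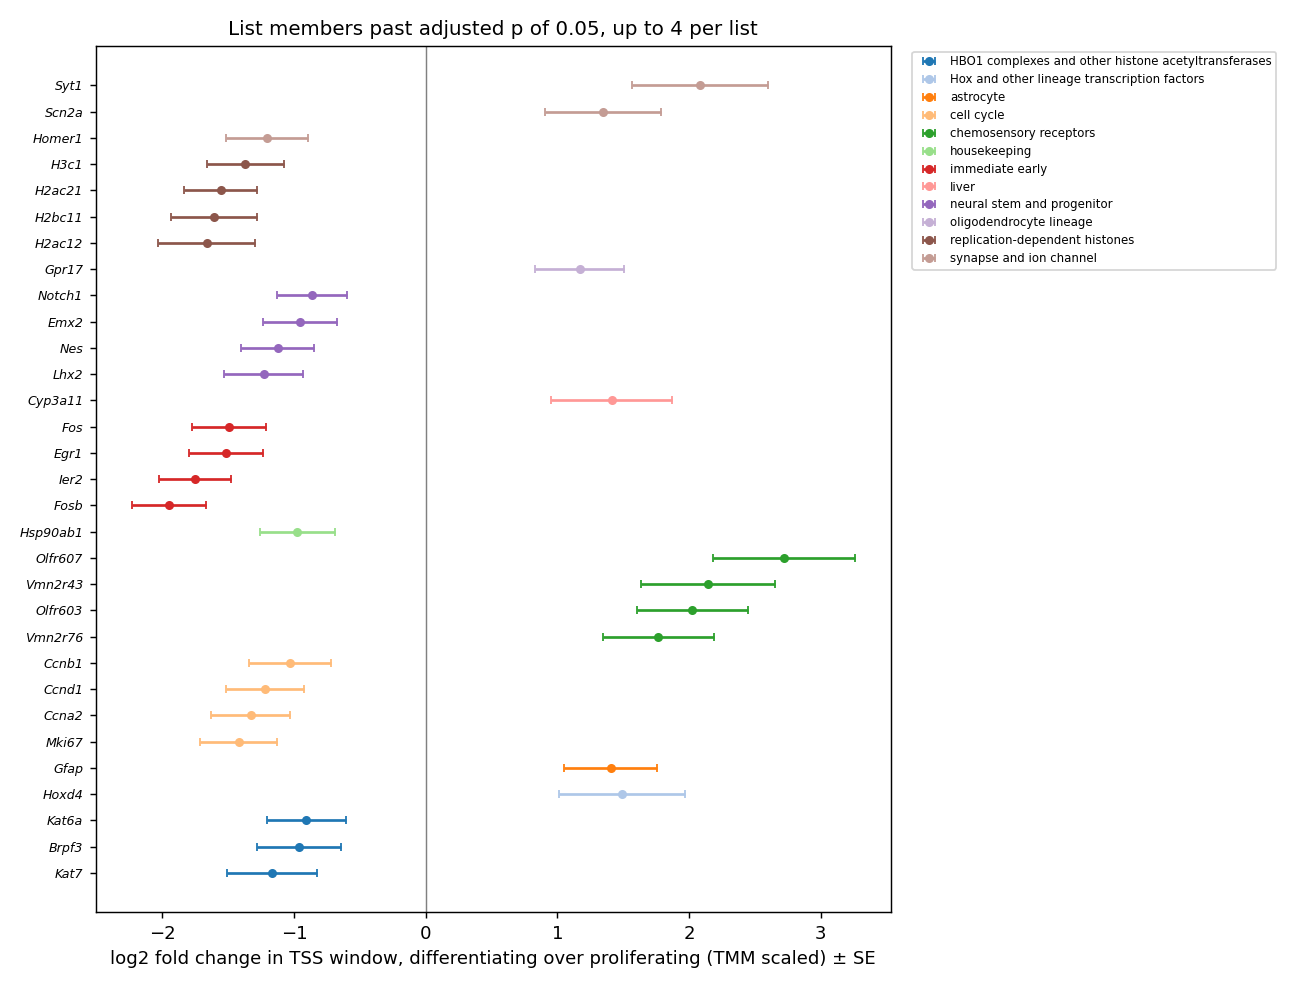
Fitted log2 fold change of the TSS window, differentiating over proliferating, with its standard error (horizontal axis) for the 31 list members past an adjusted p of 0.05, up to 4 per gene list (vertical axis, coloured by list). Immediate early, histone, cell cycle, neural stem and acetyltransferase genes lie below 0, from −1.95 (Fosb) to −0.86 (Notch1), and receptor genes lie between 1.77 and 2.72; the scaling is TMM, and all points keep their side of 0 with gene body totals.

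These calls are relative to the typical window, because TMM scaling sets the median change to 0.02; with gene body totals the median was −0.47, and 64 windows rose and 4996 fell. DESeq2 called 21 risen and 570 fallen windows, but gave no adjusted p for 16616 of the 19477, so its counts cover far fewer windows. No window was called by edgeR in the test of the stage difference over input, with 1 input library per stage (1680 at an unadjusted p under 0.05). Thinned to a common depth, 82 windows rose and 164 fell, while the medians of the windows called at full depth stayed at 1.39 and −1.02, and 56 rose and 17 fell where the count filter was applied anew and left 3899 windows. Of the 46 called genes named here 22 stayed past the threshold without each library in turn, and none under every alternative. Without 1 library the total of 1285 became 331 (without proliferating replicate 3), 439 (differentiating replicate 3), 490 (differentiating replicate 2) or 710 (proliferating replicate 2).

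Over gene bodies, 9 of 24564 rose and 31 fell between proliferating and differentiating cells. Among the named genes with a mean count of at least 30, those that fell most were the immediate early genes Ier2 (log2 −2.22, SE 0.18, edgeR adjusted p = 0.00202), Junb (−1.81, SE 0.19), Fos (−1.44, SE 0.19), Egr1 (−1.33, SE 0.19), Jun (−1.28, SE 0.17) and Fosb (−1.24, SE 0.15). Jund (−1.57, SE 0.19), a gene related to Jun outside that list, Irf2bp2 (−1.39, SE 0.15), Srf (−1.34, SE 0.16) and Ckb, brain creatine kinase (−1.26, SE 0.19), completed the named falls. Of 15 immediate early bodies 6 fell (10 over the list alone; camera adjusted p = 4.42e-14, and p = 0.0251 with an estimated correlation). Of 53 histone bodies 4 fell (44 over the list alone), H3c2 (−2.16), H2ac12 (−2.13), H2bc11 (−2.06) and H3c1 (−1.84), with a list median of −1.15 (camera adjusted p = 1.66e-35, and p = 0.0335 with an estimated correlation). Since gene bodies contain the TSS window and these genes are short, this is not independent of the windows: 28 of the 31 bodies that fell had a window that fell too, and with the window's counts taken out of the body 5 bodies rose and 2 fell. Of the 31 fallen bodies 23 could still be tested then, all 23 with a negative log2 (median −0.79, against −1.18 with the window). Of the named genes Erdr1 (3.19, SE 0.09), Usp7 (0.90, SE 0.07) and Kat6b (0.57, SE 0.07), a histone acetyltransferase, rose. Their inputs differed between the stages by 3.63, 0.91 and 0.47 on the same scale.

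Hox and lineage factor bodies rose as a list, with 49 of 50 positive, a median of 0.35 and 0 members called over all genes (6 risen over the list alone, camera adjusted p = 5.97e-13, and p = 0.0166 with an estimated correlation). Their summed counts stayed below input in both stages, at log2 −0.64 in proliferating and −0.30 in differentiating WT libraries. The differentiating IgG library stood at −0.31, so the list rose to the level of IgG, not above it. Chemosensory bodies also rose as a list, by less, with a median of 0.18 over 1308 genes (camera adjusted p = 1.02e-06, and p = 0.0251 with an estimated correlation). None of them was called on its own. Their summed counts over input were log2 0.29 (proliferating) and 0.33 (differentiating) in WT ChIP and 0.31 and 0.43 in IgG. The rise of this list was thus not particular to the H3K14ac antibody. Neural stem and progenitor bodies fell as a list (median −0.44, 25 of 27 negative, 0 called over all genes and 15 over the list alone; camera adjusted p = 1.87e-12, and p = 0.207 with an estimated correlation). Neuronal differentiation bodies rose as a list by a median of 0.11 (3 risen and 3 fallen over the list alone; camera adjusted p = 0.00517, and p = 0.123 with an estimated correlation). Ccnd1 (−0.87) was the 1 cell cycle body of 28 that fell, and that list was not called. Not called either were the synapse, oligodendrocyte, astrocyte, housekeeping, acetyltransferase, liver, striated muscle, blood cell, germline, microglia, endothelial, mesenchymal and imprinted lists. DESeq2 called 39 risen and 159 fallen bodies, edgeR on autosomes alone 28 and 122, and the edgeR test over input none (561 at an unadjusted p under 0.05). Of the 18 called genes named here 1 stayed past the threshold without each library in turn, and none under every alternative. Without 1 library the total of 40 became 3 (without proliferating replicate 3), 6 (differentiating replicate 1), 7 (proliferating replicate 2 or differentiating replicate 2) or 66 (proliferating replicate 1).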

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

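The tests of explanations for the 3 patterns below, and the list of conserved genes, were chosen after the results were seen; the splits of the libraries and the interaction with input were set before.

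The WT enrichment over input differed between the stages for several lists, by a stage by ChIP interaction with 1 input per stage. At TSS windows, the median interaction was −0.50 for neural stem genes (camera adjusted p = 0.0124, adjusted p = 0.436 with an estimated correlation), −0.65 for cell cycle genes (0.000243, then 0.178), −0.45 for housekeeping genes (0.0124, then 0.178) and −0.36 for histone acetyltransferases (0.0259, then 0.248). It was −1.37 for immediate early genes (2.33e-08, then 0.0937) and −0.80 for histones (5.37e-09, then 0.178) by the same 2 camera tests. It was positive for microglia genes (0.97; 0.0124, then 0.178) and chemosensory receptors (0.35; 6.54e-05, then 0.183). Over gene bodies it was −0.26 for neural stem genes (1.51e-09, then 0.351), 0.11 for neuronal genes (0.0028, then 0.122), −0.99 for immediate early genes (9.17e-17, then 0.0222), 0.40 for Hox and lineage factors (1.51e-09, then 0.0222) and −1.09 for histones (8.88e-34, then 0.0405). No single gene passed the interaction test in edgeR: 1680 TSS windows and 561 gene bodies had an unadjusted p under 0.05. These p-values rest on 1 input library per stage. No group had 4 or more samples in which an outlier could be sought, and no part of the data was left unanalysed.

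The first pattern is the fall of TSS counts in differentiating cells. A change already present in the input DNA is argued against by the 890 fallen windows, whose summed input counts changed by 0.0025 on the log2 scale (interval −0.03 to 0.04) while the ChIP counts fell by 1.07. Sex chromosomes are not the source, since 1206 windows were called on autosomes alone. Deeper sequencing of the differentiating libraries stays open: the slope of the TSS share on depth within the stages would give a stage difference of 0.0481 points, with a 95% interval of −1.32 to 1.42, so that it does not rule out a large part of the difference. Random thinning to equal depth left the median of the fallen windows at −1.02, which it does by construction for any cause that is not counting noise. A loss of the same share of signal at all genes stays open too: the retained share of the excess over background was higher for neural stem than for cell cycle genes, 2 lists chosen for their difference, by a gap of 0.308 over input and 0.393 over IgG, which counts against it, but each background is 1 library per stage and some shares changed much with it (housekeeping 0.124 ± 0.114 over input and 0.673 ± 0.147 over IgG), others less (immediate early 0.0231 ± 0.0651 and 0.259 ± 0.106). A smaller immunoprecipitated share in all differentiating libraries cannot be told apart from a lower level of the mark: the TSS share was 1.07 times that of input, and there is no spike-in or second batch.

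With 10 splits of the 6 libraries no share under 0.05 is possible. The real split gave 1285 TSS windows and the highest other split 5 (1 split as large), 40 gene bodies against 0 (1 split), 8 lists at TSS windows against 10 (4 splits as large) and 6 lists over gene bodies against 8 (4 splits). The other splits with as many lists were those that put WT proliferating replicate 1 together with 2 differentiating libraries. With the preset correlation, camera thus called as many lists between groups that mixed the stages. The number of lists called is therefore no measure of a stage difference.

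The second pattern is gene bodies that differ between stages. For the 9 that rose, a difference in the amount of DNA already present in input may be the source: the median input change was 0.91 (SE 0.58) against 0.90 in ChIP, with the same sign in 9 of 9. No biological explanation was tested. For the 31 that fell it is argued against, since the median input change was −0.10 (SE 0.05) and that of the ChIP −1.33, although 21 of 31 had a negative input change and for 2 of 31, among them Prickle1 (−0.81 in input, −0.68 in ChIP), it was at least 0.5 times the ChIP change.

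The third pattern is the 51 gene bodies higher in the null libraries. Whether mouse repeats that collect reads in every library were the source cannot be decided. The share of input counts in these bodies was at most 0.135 times that of the null libraries. However, the bodies were chosen for a higher share in null than in WT ChIP. The input shares (0.618% and 0.627%) lay within the range of WT ChIP (0.591% to 0.642%), so the choice alone gives a low ratio. Separate amplification in each null library is argued against by 36 bodies chosen in the proliferating null library. Their median fold in the differentiating one was 4.17 (34 of 36 above 2, while the 1290 bodies with 10 or more counts had a median of 0.957). DNA of another organism read at conserved genes remains open: of 41 actin, tubulin, heat shock protein 70, ubiquitin, calmodulin and translation factor genes, families chosen because of the calls, the 32 that were not called were 2.55 (95% Poisson interval 1.82 to 3.49) and 1.53 (1.27 to 1.84) times the WT share. These intervals cover counting error alone, not duplicated reads. The lower limit of the smaller value did not clear the bound set for it, and calmodulin genes, at 1 and 6 counts, decide nothing. Translation factor genes, which also had no called member, were 0.442 (0.0112 to 2.46) and 1.32 (0.741 to 2.18) times the WT share, so no rise was shown for them. No biological explanation was tested, since the null libraries have 1 sample per stage.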

How the results depend on the processing

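The autosome, thinning (with and without a new count filter) and TSS-window-free alternatives, and the list tests without each library, were chosen after the data were seen; the others were not. Except where said, the cause of a change was not tested.

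Stage, TSS windows (1285 called): 1297 with RLE scaling, 1408 with library totals, 1206 on autosomes and 1304 without a filter lay within 1.5 times. Gene body totals gave 5060 (64 rose, 4996 fell), DESeq2 591 (with no adjusted p for 16616 windows), a replicate block 787 (266 rose, 521 fell), all 12 libraries 592 (286 rose, 306 fell), and thinning to a common depth 73 (56 rose, 17 fell). That filter left 3899 of 19477 windows, whose median was −0.53 as reported and which TMM set to −0.0149; with the same windows tested, thinning gave 246 (82 rose, 164 fell; 224 also called at full depth), and the median of the 890 fallen windows was −0.999 as reported and −1.02 thinned, as random thinning gives by its construction. A mean of at least 50 gave 1, with fewer windows tested. Adjusting for input gave 0 in edgeR (1680 at an unadjusted p under 0.05) and for null 0 (43). Leaving out 1 library gave 331 to 1256. The block assumes that replicate numbers pair the libraries, which correlations of the same number (−0.12, 0.20 and −0.19 over gene bodies) did not show. The highest was that of proliferating replicate 1 with differentiating replicate 3 (0.27). Single-copy Y genes argue against the same cells behind the number 3, at 13.9 CPM in the proliferating and 275 in the differentiating library.

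Stage, gene bodies (40): 35 with RLE scaling, 49 with library totals, 38 with a block and 32 without a filter lay within 1.5 times. With the block 18 rose and 20 fell, where 9 rose and 31 fell in the reported test. DESeq2 gave 198, all 12 libraries 110, autosomes 150, thinning 17, or 14 with the same bodies tested, a mean of at least 50 23, adjusting for null 5 and for input 0 (561 at an unadjusted p under 0.05 in edgeR). Gene bodies without the TSS window gave 7: of the 31 that fell, 6 had no count left and 23 were tested, with a median of −0.79 in place of −1.18. Leaving out 1 library gave 3 to 66.

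WT against null: at TSS windows (2) DESeq2 gave 4, no filter 6 and a mean of at least 50 0; at gene bodies (51) DESeq2 gave 81, and leaving out 1 library 36 to 60. WT against IgG: at TSS windows (702) TMM gave 53, RLE 54, DESeq2 371 (with no adjusted p for 11990 of 13158 windows), no stage term 67 and a mean of at least 50 5, and leaving out 1 library 5 to 1035. At gene bodies (303) DESeq2 gave 491 (with no adjusted p for 4186 of 23685 bodies), all 12 libraries 465 and no stage term 190, and leaving out 1 library 74 to 701. WT against input: at TSS windows (2697) no stage term gave 54 and a mean of at least 50 6, and leaving out 1 library 25 to 3990; at gene bodies (7398) leaving out 1 library gave 0 to 10231. Leaving out the control of 1 stage leaves the other stage alone to give the difference.

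Lists: at TSS windows 8 were called by stage with a preset correlation, 2 with an estimated one, 6 with fry, 8 with a block and 6 to 8 without 1 library. Over gene bodies 6 were, 4 with an estimated correlation and 6 to 8 without 1 library. An estimated correlation took lists against null from 2 to 0 (TSS windows) and 3 to 0 (gene bodies), and against input from 11 to 0 and 9 to 1. The TSS share by stage was −1.44 to −1.22 points without 1 library. For WT against controls the difference in the median log2 ratio was 0.0541 (exact permutation p = 0.909), which the near-empty null libraries set in part, so it decides nothing. Without 1 library the difference in the TSS share was 0.854 to 1.19 points.

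Reversed genes: at stage TSS windows, Erdr1 was −0.0670 adjusted for input and −3.57 for null, and Zfp981 −5.03, Zfp979 −6.51, Gpr17 −5.20 and Ccnb1 5.85 for null. The values adjusted for null rest on 1 null library per stage, in which a tested window held 0.0933 and 0.483 counts on average. Their size and sign thus decide nothing. Without 1 library, Gpr17 stayed at 0.94 to 1.35 and Ccnb1 at −1.17 to −0.87. At stage gene bodies, Erdr1 was −0.46 and Usp7 −0.0221 adjusted for input. Against null, TMM and RLE gave 0.66 and 0.65 for ND3, 0.69 and 0.68 for ND4L, 0.71 and 0.71 for COX1 and 0.70 and 0.69 for ND4, and Kat7 gene bodies ranged from −1.07 to 0.0383 without 1 library. Against IgG, the Kat7 window was −0.12 with TMM, −0.14 with RLE and −0.38 to 1.15 without 1 library. Of the values of single genes and lists 3042 kept their direction and side of the threshold, 936 kept the direction only, 2 newly passed and 20 reversed. A list that changed direction without passing in either test was counted among the 3042, not among the reversed. Of the called genes named, those past the threshold without each library in turn were 22 of 46 for stage TSS windows, 1 of 18 for stage bodies, 7 of 8 for null bodies, 0 of 31 and 8 of 17 for IgG, and 1 of 42 and 0 of 76 for input (windows, then bodies). Depth limits the null comparison, with 67.6% of tested windows at 0 in both null libraries.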

Other observations

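Values that belong to no comparison follow, without a test. Single-copy Y chromosome genes held 62.1, 15.3 and 13.9 CPM of gene body counts in the proliferating WT libraries, 14.9, 15.6 and 275 in the differentiating ones, 9.94 and 12.6 in input, 249 and 292 in IgG and 46.8 and 184 in the null libraries (3 and 59 counts). The X chromosome held 2.49%, 3.59% and 3.31% of counts in the proliferating and 3.64%, 3.95% and 2.34% in the differentiating WT libraries, 3.22% and 3.53% in input, 2.00% and 2.40% in IgG and 3.37% and 3.25% in the null libraries. The input columns carry the number of WT replicate 1, whose Y values were 62.1 in the proliferating ChIP against 9.94 in its input and 14.9 in the differentiating ChIP against 12.6. The sex of the foetuses is not in the labels.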
